A study of Homo sapiens with 12 samples.

How the data were processed

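The series held RNA-seq of 4 human breast cell lines that its design calls triple-negative, with 3 biological replicates each: A10 (MCF10A), NeoT (MCFNeoT), T1 (MCFT1) and CA1 (MCFCA1). Per the labels, total RNA was treated with DNase I, and libraries were made with an NEBNext Ultra kit and sequenced on an Illumina instrument. The deposited table gives estimated counts (expected counts) per gene for 12 libraries, made by Salmon as the table's name says and not scaled between libraries. The submitters' notes name GRCh38 and limma without a role, and the annotation and versions are not given. The table had 29744 gene rows, of which 10300 had no count in any library, and 10.1% of its values were not whole. Values were rounded to whole counts, which changed none by more than 0.5. The 114 rows that share a gene name with another were kept as they stand. Positions come from a GRCh38 annotation, matched by symbol for 23192 rows and by synonym for 1783, with 4769 rows unmatched. Older symbols of the table were kept.

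Library totals ran from 18032399 to 35730423 counts. Genes were filtered with edgeR's filterByExpr on the line, which left 14417, and scaled with TMM factors. An edgeR 4.0.16 quasi-likelihood model (R 4.3.3) with a mean per line and robust dispersions was fitted to all 12 libraries, so that the lines share an estimate of spread. NeoT, T1 and CA1 were each compared with A10, and T1 with NeoT and CA1 with T1 as consecutive steps in the order of the series design. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Genes changed at least 2-fold were counted by the fitted fold. A test of all 3 contrasts with A10 together gave the genes differing among the 4 lines. Calls shared between comparisons were counted per direction, beside the product of their rates for independent lists and 20 simulations of unchanged groups against the same libraries. Folds in the text are fitted values. Where a line had 0 counts the fold is a bound against 3 counts over the line, and where it had 1 to 3 counts it is a ratio of CPM with an exact 95% counting interval.

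Of 30 gene lists, written before the data were examined with 604 genes, 584 genes had a row. The list of 13 mitochondrially encoded mRNAs had no rows and was not analysed, so 29 lists were tested with camera (limma 3.58.1; inter-gene correlation preset at 0.01, two-sided, adjusted over the lists of a comparison). Each was also tested with an estimated correlation and with fry, which tests a list's direction and does not compare it with other genes. The adjusted p of lists are those with the preset correlation unless said otherwise. They can be many orders of magnitude smaller than with an estimated one, so they do not rank the strength of evidence. As the mitochondrial mRNAs had no rows, the mitochondrial share was measured on 2 mitochondrial rRNA rows in their place. It was compared between lines with an exact permutation test of the F statistic. Pearson's r between libraries was taken on log2 CPM with a prior count of 2.

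The choices of model, threshold, comparisons, lists, alternatives and named genes were made before the data were examined. The genes named were HRAS in every comparison; the 10 with the largest rise and the 10 with the largest fall in each comparison with A10, and 8 and 8 in each consecutive step; up to 4 members with the smallest adjusted p of each list described; and 5 per direction among genes changed at all 3 steps and among genes shared by all 3 comparisons with A10. Those ranked by size had to be called, to have a named protein-coding symbol, at least 10 CPM in the higher line and no overlap between the replicates of the lines. For genes shared by all 3 comparisons, 10 CPM was asked only of the highest of the 4 lines, and overlap was not checked. Members of a list at 0 in a line were taken at their bound in a second median. The 6 genes drawn in a figure were chosen from these after their values were seen.

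The alternatives were RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit to only the libraries compared, the replicate number as a block, each library left out in turn, and glmTreat against a 2-fold change. Agreement between replicates was also taken as Spearman's rho and over genes of at least 10 CPM. After seeing the data, fits without the cytoplasmic rRNA rows and without both T1 replicate 1 and NeoT replicate 3 were added. Simulated counts were drawn from the fitted model with 100 genes changed 2-fold and 100 changed 4-fold in NeoT alone, among genes of at least 1 CPM. There edgeR recovered 84% of 2-fold and 98% of 4-fold changes, and 7.14% of its calls were false. The real lines differ in far more genes, so these rates need not hold for them. Other work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The DNA and protein parts of the preparation are not in this series.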

Results

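RNA was sequenced from 4 human breast epithelial cell lines, with 3 biological replicate libraries per line and 12 libraries in all. A10 is MCF10A, a mammary line that does not form tumours. NeoT is MCFNeoT, a derivative made by giving MCF10A a mutant HRAS and named benign hyperplasia in the series design. T1 (MCFT1, atypical hyperplasia) and CA1 (MCFCA1, invasive) descend from it through passage as xenografts. The stated purpose was the quality and reproducibility of a preparation that takes DNA, RNA and peptides from the same sample. Replicates 1 to 3 held 35730423, 22274719 and 25359708 counts in A10 and 24903113, 24560883 and 18032399 in NeoT. They held 28967353, 30406184 and 23528574 counts in T1 and 18465144, 24503070 and 25294008 in CA1. Between 12660 and 13902 genes had at least 10 counts in a library. Values below are CPM (counts scaled by TMM to a common library size) as mean ± SD over 3 libraries (n = 3) unless said otherwise. A gene with 0 counts in all libraries of a line may still have stood at up to 0.0326 CPM in A10, 0.0474 in NeoT, 0.0356 in T1 and 0.0463 in CA1, the level of 3 counts over the line. Folds against such a line are given as lower bounds. These floors and all counting intervals cover counting error only.

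The 2 mitochondrial rRNA genes took different shares of the counts in the 4 lines: 0.158% ± 0.0062 in A10, 0.445% ± 0.0603 in NeoT, 0.253% ± 0.0164 in T1 and 0.336% ± 0.0361 in CA1 (SD, n = 3). An exact permutation test of the F statistic over all 369600 assignments of libraries to lines gave p = 6.494e-05, the smallest that these assignments can give. It was the only test on shares of counts. The 4 cytoplasmic rRNA rows took 1.99% ± 0.132 of counts in A10, 1.79% ± 0.358 in NeoT and 1.12% ± 0.211 in CA1. In T1 their share was 7.76% in replicate 1 (95% Wilson interval 7.754% to 7.773%), 1.65% in replicate 2 (1.646% to 1.655%) and 2.10% in replicate 3 (2.094% to 2.105%). The 10 most abundant genes other than rRNA held 6.57% of the remaining counts in A10, 10.1% in NeoT, 7.05% in T1 and 8.04% in CA1.

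**Figure D1:**
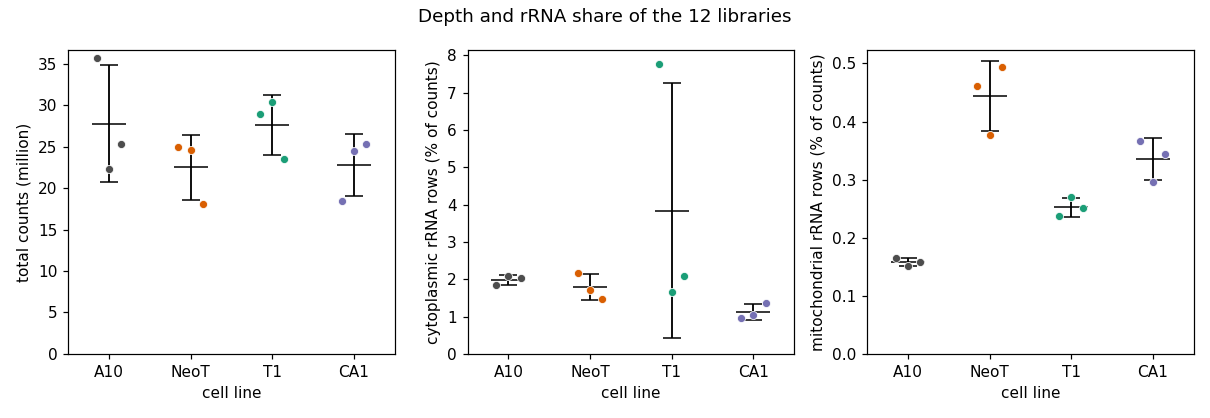
Total counts per library (left), the share of counts on 4 cytoplasmic rRNA rows in percent (middle) and on 2 mitochondrial rRNA rows in percent (right) for each line. Points are single libraries, and bars are the mean with its SD over 3 libraries. T1 replicate 1 stands at 7.76% cytoplasmic rRNA, and the mitochondrial rRNA share is lowest in A10 (0.158%) and highest in NeoT (0.445%).

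Replicate libraries of a line lay closer to each other than to libraries of other lines. Across 14417 tested genes, Pearson's r of log2 CPM between replicates ran from 0.9776 to 0.9891 with a median of 0.9864 over 12 pairs, and between lines from 0.8081 to 0.905 over 54 pairs. NeoT replicate 3 had the lowest values with its replicates, 0.9776 and 0.9784, against 0.9831 or more in the other pairs. Genes are not independent replicates, so these values describe and do not test. T1 and CA1 were the closest pair of lines (mean r = 0.9025), followed by A10 and T1 (0.900), while the other pairs lay lower: NeoT had 0.842 with A10, 0.8379 with T1 and 0.8123 with CA1, and A10 and CA1 had 0.8366. The first principal component held 44.9% of the variance and ran from NeoT, which stood apart, through A10 and T1 to CA1. The second, with 31.9%, ran from A10 through T1 and NeoT to CA1. The biological coefficient of variation was 8.64% in A10, 15.9% in NeoT, 8.32% in T1 and 6.41% in CA1. In all, 12953 of 14417 genes differed among the 4 lines.

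**Figure D2:**
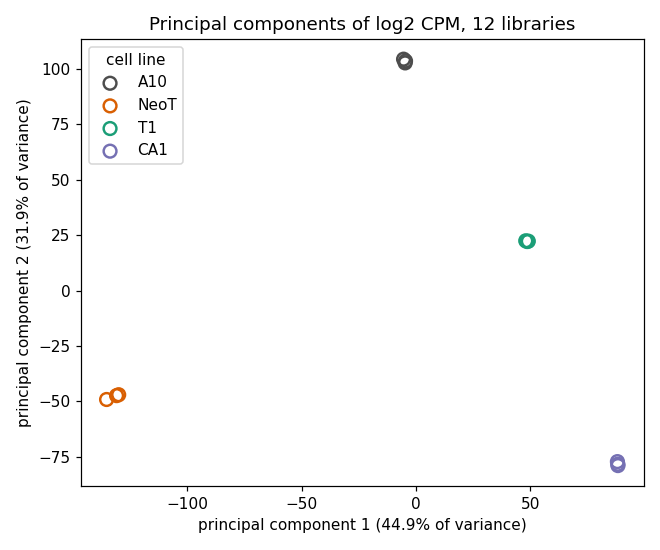
Scores of the 12 libraries on the first 2 principal components of log2 CPM, with the share of variance on each axis and 1 circle per library, coloured by line. The 3 libraries of each line overlap, and the lines lie apart.

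HRAS (chromosome 11, 532242 to 535576, GRCh38), whose mutant form was used to make the derived lines, was higher in each of them than in A10. It stood at 64.5 ± 4.59 CPM in A10, 239.5 ± 21.7 in NeoT (3.72-fold higher, adjusted p = 2.24e-13), 158 ± 11.9 in T1 (2.45-fold, adjusted p = 1.19e-10) and 302 ± 11.9 in CA1 (4.68-fold, adjusted p = 2.66e-14). Between consecutive lines it fell by 0.60 on the log2 scale from NeoT to T1 (adjusted p = 1.68e-06) and rose by 0.93 from T1 to CA1 (adjusted p = 7.33e-09). The counts do not separate the mutant from the normal transcript.

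**Figure D3:**
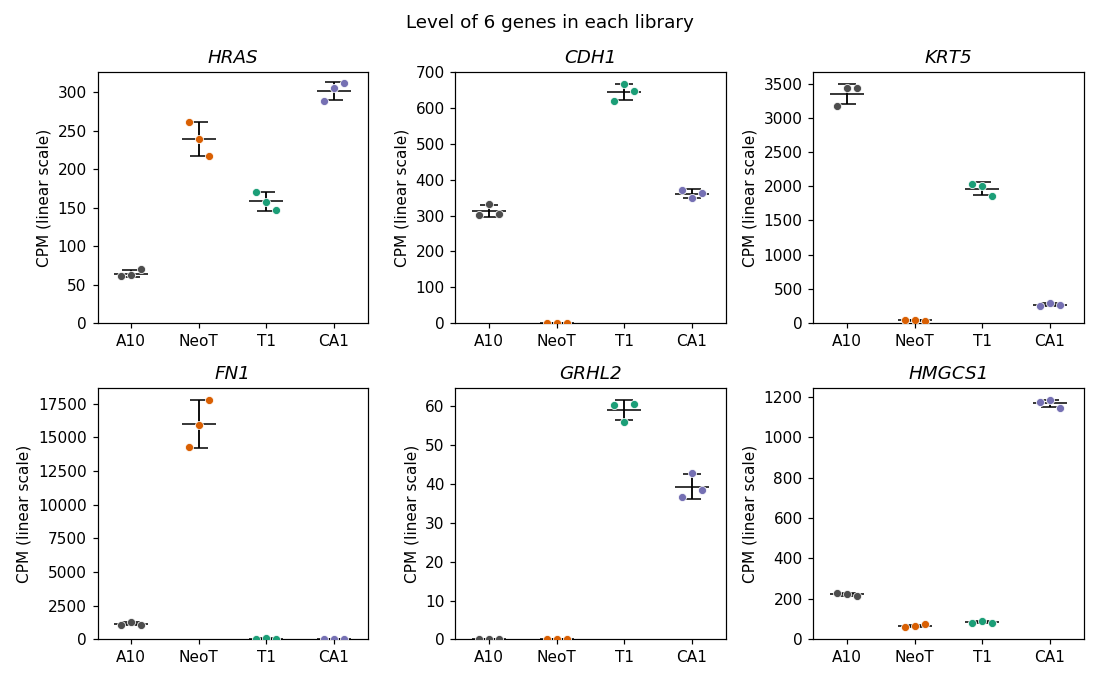
CPM on linear axes from 0 for HRAS, CDH1, KRT5, FN1, GRHL2 and HMGCS1 in each line; points are single libraries and bars are the mean with its SD over 3 libraries. HRAS is lowest in A10 (64.5 CPM), CDH1 is near 0 in NeoT (0.691), FN1 is highest in NeoT (15980), GRHL2 is at 0 in A10 and NeoT, and HMGCS1 is highest in CA1 (1167).

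NeoT against A10 asks what differs between the HRAS-transformed line and its parent. Most epithelial transcripts of A10 were lower in NeoT. CDH1 (E-cadherin) stood at 0.691 ± 0.452 CPM in NeoT and 313 ± 16.3 in A10, a 477-fold difference, and the tight junction gene CLDN1 at 0.573 ± 0.339 and 282 ± 13.5 (467-fold). The basal cytokeratin KRT5 fell 83.2-fold, from 3346 ± 152 to 40.2 ± 3.49 CPM, and TP63, a transcription factor of basal epithelium, had 0 counts in NeoT and 107 ± 2.23 CPM in A10, at least 2260-fold lower. FN1 (fibronectin; chromosome 2, 215360865 to 215436068) rose 13.8-fold, from 1157 ± 104 to 15980 ± 1763 CPM. In all, 10144 of 14417 genes changed, 4854 up and 5290 down, and 4942 of them by at least 2-fold (2186 up, 2756 down).

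Of 22 measured epithelial junction and identity genes, 21 fell in NeoT and 0 rose (21 also when adjusted over the list alone), with a median log2 fold change of -5.51, or -5.19 with genes at 0 placed at their bound (camera adjusted p = 3.5e-35). MAL2 fell 63.4-fold and ESRP1, a splicing regulator of epithelia, 259-fold. With an estimated correlation the camera adjusted p of the epithelial junction, basal and squamous lists in NeoT was 6.0e-04 each. Basal epithelial markers fell in 17 of 20 cases and rose in 3 (20 called over all genes and 20 adjusted over the list alone, median -4.34, adjusted p = 2.0e-41); KRT15 fell 736-fold, COL17A1 1176-fold and KRT17 213-fold. Squamous differentiation genes fell in 16 of 19 cases and rose in 0 (16 adjusted over the list alone, median -8.20, or -5.56 with bounds, adjusted p = 7.9e-16). Among them, the kallikrein protease genes KLK7 and KLK5 were at least 2498-fold and 863-fold lower. SPRR1B was at least 1729-fold lower, and TGM1 fell 435-fold. Luminal markers fell in 9 of 16 cases and rose in 4 (13 adjusted over the list alone, median -2.34, adjusted p = 4.6e-04). CD24 fell 51.3-fold, ELF3 29.98-fold and MUC1 14.8-fold, while KRT8 rose 3.22-fold, to 473 ± 45.2 CPM.

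Mesenchymal markers rose in 15 of 22 cases and fell in 5 (21 adjusted over the list alone, median 1.96, adjusted p = 1.3e-05). LOX, which cross-links collagen, rose 28.5-fold to 674 ± 56.8 CPM and VIM (vimentin) 2.93-fold, but SPARC fell 87.0-fold. TGF-beta targets rose in 14 of 21 cases and fell in 3 (17 adjusted over the list alone, median 1.06, adjusted p = 2.3e-04), with TGFBI up 4.24-fold, ID1 2.72-fold, LTBP2 2.59-fold and TGFB2 itself 6.01-fold. Among markers of other cell types, all 6 measured adipocyte genes rose (6 adjusted over the list alone, median 4.96, or 4.56 with bounds, adjusted p = 4.5e-04). PPARG rose 9.75-fold to 48.0 ± 4.78 CPM, FABP4 rose 56.7-fold. CIDEC had a ratio of 1105 (95% counting interval 305 to 9135) and PLIN1 of 324 (110 to 1576). The adipocyte call was lost with an estimated correlation (adjusted p = 0.072). Of 9 stromal fibroblast markers 2 rose and 3 fell (5 adjusted over the list alone, adjusted p = 0.94), DCN rising 9.15-fold to 632 ± 34.0 CPM and COL1A1 standing at 8.14 ± 0.307. Of 7 leukocyte markers 2 rose and 4 fell (6 adjusted over the list alone, adjusted p = 0.54), with CD68 up 19.2-fold. Of 4 endothelial markers 1 rose and 2 fell (3 adjusted over the list alone, adjusted p = 0.94).

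MAPK feedback and output genes, which read out signalling below RAS, rose in 12 of 16 cases and fell in 3 (15 adjusted over the list alone, median 0.85, adjusted p = 1.6e-05). DUSP4 rose 10.02-fold to 1093 ± 35.7 CPM, SPRY4 6.99-fold, DUSP5 3.55-fold and DUSP6 2.99-fold. NRF2 targets rose in 17 of 21 cases and fell in 4 (21 adjusted over the list alone, median 1.05, adjusted p = 2.0e-10), led by AKR1C1 (26.8-fold, to 984 ± 33.6 CPM) and AKR1C2 (8.07-fold). AKR1C1 and AKR1C2 are close paralogs that can share reads.

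All 30 S phase and mitosis genes fell (30 adjusted over the list alone, median -2.01, adjusted p = 5.8e-23), with PLK1 down 9.29-fold to 13.7 ± 0.468 CPM, CENPF 7.93-fold, CDC20 5.86-fold and PCNA 5.42-fold. Interferon-stimulated genes fell in 23 of 28 cases and rose in 2 (25 adjusted over the list alone, median -2.43, adjusted p = 5.9e-06). OAS1 fell 19.3-fold, SAMD9 15.9-fold and OAS3 10.8-fold, against a 13.1-fold rise of IFI44L. Inflammatory and NF-kB genes fell in 12 of 22 cases and rose in 6 (18 adjusted over the list alone, median -1.79, adjusted p = 2.4e-05), with LCN2 down 193-fold, ICAM1 63.0-fold, IL1A 23.6-fold and IL1B 15.1-fold. Cholesterol synthesis genes fell in 15 of 22 cases and rose in 3 (20 adjusted over the list alone, median -0.67, adjusted p = 0.0025), with FDPS down 4.48-fold and HMGCS1 3.37-fold, while INSIG1 rose 2.55-fold.

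Beside CIDEC and PLIN1 above, the largest rises by the naming rule included EPDR1 (at least 1037-fold) and TBX18 (at least 453-fold), both at 0 in A10. LY75 had a ratio of 2694 (95% counting interval 745 to 22252) and SFTPB of 1150 (206 to 45460). IL1RL1, the receptor for IL-33, rose 693-fold to 71.1 ± 1.58 CPM, GALNT15 626-fold, LAMA4 (a laminin chain) 624-fold and AOC3 419-fold. Beside KLK7, TP63, SPRR1B and KLK5 above, the largest falls were KLK10 (at least 3079-fold), MPZL2 (at least 2639-fold), the cyclin gene CCND2 (at least 1770-fold), PDPN (at least 971-fold), AP1M2 (at least 718-fold) and ZBED2 (at least 616-fold), all at 0 in NeoT. Of 29 tested lists, 13 passed with the preset correlation and 12 of them also with an estimated one. The p-values of single genes rest on a spread between replicate libraries that the 4 lines share, and those of camera compare a list with other genes. None of them can tell a line from the culture it was taken from. Over all 4 lines the biological coefficient of variation was 10.37%. That is below the 15.89% of NeoT and above the 8.64% of A10, 8.32% of T1 and 6.41% of CA1. Gene p-values may therefore be too small in comparisons with NeoT and too large in the others.

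T1 against A10 asks what differs between the atypical hyperplasia line and the parent. T1 kept the epithelial junction genes that were low in NeoT and expressed several above A10. GRHL2, a transcription factor of epithelial identity (chromosome 8, 101492439 to 101681200), stood at 59.0 ± 2.59 CPM in T1 and had 0 counts in A10, at least 1803-fold higher. EPCAM rose 5.73-fold to 239 ± 5.41 CPM, and the luminal cytokeratin KRT8 rose 11.3-fold, from 147 ± 13.02 to 1657 ± 43.4 CPM. VIM fell 8.06-fold, from 762 ± 21.8 to 94.5 ± 2.57 CPM, and FN1 17.8-fold to 65.1 ± 3.47 CPM. In all, 7479 genes changed, 3753 up and 3726 down, and 2716 of them by at least 2-fold (1362 up, 1354 down).

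Epithelial junction genes rose in 20 of 22 cases and fell in 0 (21 called when adjusted over the list alone, median 1.03, adjusted p = 3.2e-21). RAB25 rose 23.8-fold to 94.9 ± 4.19 CPM and CLDN7 3.58-fold. Luminal markers rose in 14 of 16 cases and fell in 0 (14 adjusted over the list alone, median 1.71, adjusted p = 5.5e-14), with ELF3 up 4.53-fold, CD24 3.65-fold and KRT18 2.80-fold. Mesenchymal markers fell in 15 of 22 cases and rose in 3 (19 adjusted over the list alone, median -1.17, adjusted p = 2.3e-10). DCN fell 152-fold, and MMP2 rose 3.40-fold to 94.0 ± 5.35 CPM. Stromal fibroblast markers fell in 7 of 9 cases and rose in 0 (8 adjusted over the list alone, median -4.45, adjusted p = 7.0e-11), with POSTN down 133-fold, C1S 29.1-fold and C1R 21.9-fold. DCN and POSTN stand in both lists.

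Basal markers split: 11 of 20 rose and 6 fell (17 adjusted over the list alone, median 0.27, adjusted p = 0.049). KRT6B rose 13.5-fold, KRT16 7.31-fold and KRT15 6.35-fold to 5110 ± 206 CPM, while KRT14 fell 17.8-fold to 25.3 ± 1.29 CPM. KRT6B shares much of its sequence with KRT6A. The basal call was lost with an estimated correlation (adjusted p = 0.26) and when any 1 of 6 libraries was left out (adjusted p 0.052 to 0.084; A10 replicates 1 and 3, NeoT replicate 2, CA1 replicates 1, 2 and 3). Squamous genes rose in 8 of 19 cases and fell in 9 (17 adjusted over the list alone, median -0.46, adjusted p = 0.75). KLK6 rose 105-fold, KLK5 18.3-fold and KLK7 6.04-fold, and S100A7 was at least 1067-fold lower.

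MAPK feedback genes rose in 11 of 16 cases and fell in 1 (13 adjusted over the list alone, median 0.62, adjusted p = 1.0e-06), with DUSP4 up 4.15-fold, SPRY2 2.65-fold and the cyclin gene CCND1 3.43-fold to 1174 ± 3.40 CPM. Ligands of the EGFR family rose in 5 of 7 cases and fell in 1 (6 adjusted over the list alone, median 0.65, adjusted p = 0.0040), with HBEGF up 3.29-fold and EPGN 1.94-fold. Immediate early and heat shock genes rose in 12 of 22 cases and fell in 4 (16 adjusted over the list alone, median 0.28, adjusted p = 0.0062). FOS rose 4.36-fold, EGR3 3.45-fold and EGR1 2.50-fold. That call was lost with an estimated correlation (adjusted p = 0.068). YAP targets rose in 10 of 21 cases and fell in 4 (14 adjusted over the list alone, median 0.18, adjusted p = 0.044), with IGFBP3 up 3.79-fold and F3 2.17-fold. The YAP call was lost with an estimated correlation (adjusted p = 0.11) and without A10 replicate 1, A10 replicate 3 or T1 replicate 2 (adjusted p 0.052 to 0.054).

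Interferon-stimulated genes rose in 19 of 28 cases and fell in 4 (23 adjusted over the list alone, median 1.09, adjusted p = 2.6e-05). IFI27 rose 7.99-fold, IFI44L 5.87-fold, IFI6 5.35-fold and IFIT2 4.60-fold. Antigen presentation genes fell in 12 of 18 cases and rose in 0 (12 adjusted over the list alone, median -0.67, adjusted p = 2.6e-05), with HLA-B down 5.83-fold to 52.1 ± 1.34 CPM and B2M 1.64-fold. That call was lost with an estimated correlation (adjusted p = 0.068). Inflammatory and NF-kB genes fell in 16 of 22 cases and rose in 2 (20 adjusted over the list alone, median -2.25, adjusted p = 1.5e-17). The cytokine gene CSF3 fell 3282-fold from 211 ± 17.4 CPM, ICAM1 227-fold, IL1B 6.28-fold and IL1A 5.64-fold.

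S phase and mitosis genes fell in 28 of 30 cases and rose in 0 (28 adjusted over the list alone, median -1.05, adjusted p = 2.6e-15), with CENPF down 4.38-fold, PLK1 2.75-fold and CDC20 2.71-fold. Cholesterol synthesis genes fell in 15 of 22 cases and rose in 1 (18 adjusted over the list alone, median -0.35, adjusted p = 3.4e-04), with SQLE down 2.74-fold and HMGCS1 2.64-fold. Serine synthesis and ATF4 targets rose in 16 of 22 cases and fell in 2 (18 adjusted over the list alone, median 0.62, adjusted p = 6.2e-05), with ATF3 up 5.38-fold, VLDLR 4.76-fold, ASNS 2.40-fold and PSAT1 2.10-fold. All 7 measured genes near the 9p21 locus of CDKN2A rose (7 adjusted over the list alone, median 1.54, adjusted p = 0.0069), with KLHL9 up 2.99-fold and FOCAD 2.60-fold. The rise was not confined to them: 10-Mb windows of chromosome 9 starting at 1 and 30000001 had median log2 fold changes of 1.09 and 0.51. Windows from 70000001 on had -0.023 to 0.174. Adipocyte markers rose in 4 of 6 cases and fell in 1 (5 adjusted over the list alone, median 2.44, adjusted p = 8.2e-05), with PPARG up 8.20-fold and PLIN4 3.60-fold. With an estimated correlation the adipocyte list had an adjusted p of 0.0497. LPL (lipoprotein lipase) was at least 747-fold higher. PECAM1 rose 41.6-fold to 85.6 ± 3.56 CPM, while the 4 endothelial markers as a list had an adjusted p of 0.0568 (1 rose and 1 fell, 2 adjusted over the list alone), and of 7 leukocyte markers 3 rose and 3 fell (6 adjusted over the list alone, adjusted p = 0.63).

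Other large rises were ATP10A (at least 1301-fold), EPDR1 (at least 1242-fold), TBX18 (at least 422-fold) and GSPT2 (at least 355-fold). LY75 had a ratio of 5028 (95% counting interval 1391 to 41521) and the mucin gene MUC5B of 3001 (538 to 118564), and WFDC2 rose 451-fold to 214 ± 10.04 CPM. Beside CSF3 and S100A7 above, the largest falls were FGFR3, a fibroblast growth factor receptor (at least 2410-fold, from 87.3 ± 8.23 CPM), PDPN (at least 1290-fold), H2AFY2 (at least 765-fold), PCSK1N (at least 760-fold), PGBD5 (at least 577-fold), FLI1 (at least 359-fold) and LARGE (at least 354-fold). CCND2 had a ratio of 7054 (1266 to 278636). The histone gene HIST2H2AA4 had at least 409 times its A10 level in T1, at 12.7 ± 10.4 CPM, but it is a near-identical copy of HIST2H2AA3. Its adjusted p of 0.0499 rose to between 0.052 and 0.11 when any 1 of 9 libraries was left out (all but NeoT replicate 3 and CA1 replicates 2 and 3). Of 29 lists, 17 passed with the preset correlation and 13 of them with an estimated one.

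CA1 against A10 asks what differs between the invasive line and the parent. Genes of cholesterol synthesis and several luminal and epithelial genes were higher in CA1, and mesenchymal, inflammatory and replication genes were lower. HMGCS1, an early enzyme of cholesterol synthesis, rose 5.22-fold to 1167 ± 18.7 CPM, and SCD, the stearoyl-CoA desaturase (chromosome 10, 100347233 to 100364826), 9.69-fold from 1267 ± 34.9 to 12270 ± 152 CPM. KRT8 rose 25.1-fold to 3699 ± 208 CPM and KRT18 9.11-fold to 3188 ± 152. FN1 fell 34.1-fold to 34.0 ± 3.29 CPM, and CEACAM5, an adhesion molecule of carcinomas, stood at 241 ± 9.88 CPM with 0 counts in A10 (at least 7339-fold higher). In all, 10223 genes changed, 4962 up and 5261 down, and 4908 of them by at least 2-fold (2329 up, 2579 down).

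Cholesterol synthesis genes rose in 20 of 22 cases and fell in 2 (22 adjusted over the list alone, median 1.51, adjusted p = 6.3e-13), with INSIG1 up 7.69-fold and FDFT1 5.59-fold. Fatty acid synthesis genes rose in 11 of 16 cases and fell in 4 (15 adjusted over the list alone, median 0.94, adjusted p = 0.011). ACSS2 rose 12.9-fold, while FADS2 fell 8.67-fold and SCD5 7.44-fold. The fatty acid call was lost with an estimated correlation (adjusted p = 0.13). NRF2 targets rose in 14 of 21 cases and fell in 5 (19 adjusted over the list alone, median 0.79, adjusted p = 0.0020), with ABCC3 up 5.01-fold, PIR 4.19-fold and TKT 3.58-fold. Adipocyte markers rose in 5 of 6 cases and fell in 0 (5 adjusted over the list alone, median 3.03, adjusted p = 0.0024), with PPARG up 19.8-fold to 97.3 ± 4.73 CPM and PLIN4 8.20-fold. The adipocyte call was lost with an estimated correlation (adjusted p = 0.082).

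MAPK feedback genes rose in 14 of 16 cases and fell in 1 (15 adjusted over the list alone, median 1.66, adjusted p = 4.7e-11). DUSP4 rose 11.2-fold to 1220 ± 25.8 CPM, EPHA2 6.63-fold, PHLDA1 6.004-fold and DUSP5 5.52-fold. EGFR ligands rose in 5 of 7 cases and fell in 1 (6 adjusted over the list alone, median 0.62, adjusted p = 0.0091), with EREG up 9.44-fold, HBEGF 6.69-fold and TGFA 3.21-fold, while EPGN fell 6.58-fold. Targets of p53 rose in 14 of 20 cases and fell in 4 (18 adjusted over the list alone, median 0.45, adjusted p = 0.032). GDF15 rose 28.7-fold to 4803 ± 165 CPM and DDB2 2.89-fold. The p53 call was lost with an estimated correlation (adjusted p = 0.10).

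Epithelial junction genes rose in 15 of 22 cases and fell in 1 (16 adjusted over the list alone, median 1.05, adjusted p = 3.1e-10), with RAB25 up 33.3-fold, EPCAM 9.48-fold and ESRP1 7.40-fold. GRHL2 was at least 1210-fold higher. Luminal markers rose in 10 of 16 cases and fell in 3 (13 adjusted over the list alone, median 1.33, adjusted p = 0.0059). MUC1 fell 339-fold to 0.536 ± 0.279 CPM. Squamous genes fell in 13 of 19 cases and rose in 6 (19 adjusted over the list alone, median -2.54, adjusted p = 0.0022), with KLK7 down 674-fold and TGM1 351-fold, while KLK6 rose 118-fold and KLK5 5.29-fold. Basal markers rose in 10 of 20 cases and fell in 9 (19 adjusted over the list alone, median 0.18, adjusted p = 0.99), with KRT14 down 135-fold and KRT5 12.4-fold. KRT6A fell 108-fold and its close paralog KRT6B rose 38.1-fold.

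Mesenchymal markers fell in 14 of 22 cases and rose in 4 (18 adjusted over the list alone, median -1.84, or -1.41 with bounds, adjusted p = 4.2e-06). TWIST2 fell 39.95-fold and SNAI2 4.33-fold, and DCN was at least 1493-fold lower. Stromal fibroblast markers fell in 6 of 9 cases and rose in 0 (6 adjusted over the list alone, median -4.72, or -4.23 with bounds, adjusted p = 3.8e-07), with C1R down 72.7-fold and FAP 10.7-fold. POSTN was at least 1356-fold lower. Inflammatory and NF-kB genes fell in 15 of 22 cases and rose in 3 (19 adjusted over the list alone, median -2.28, adjusted p = 1.3e-06). CSF3 was at least 4491-fold lower, CXCL1 fell 33.1-fold and BIRC3 6.23-fold, and IL1B rose 3.66-fold to 403 ± 7.88 CPM. All 30 S phase and mitosis genes fell (30 adjusted over the list alone, median -1.41, adjusted p = 2.3e-17), with UHRF1 down 9.05-fold, RRM2 6.30-fold, MCM4 5.73-fold and PCNA 3.17-fold.

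Interferon-stimulated genes fell in 18 of 28 cases and rose in 4 (22 adjusted over the list alone, median -0.93, adjusted p = 0.032), with IFI27 down 9.16-fold, IFIT2 6.28-fold and IFIT3 6.02-fold. The interferon call was lost with an estimated correlation (adjusted p = 0.065) and without NeoT replicate 3 (adjusted p = 0.062). Hypoxia genes fell in 8 of 17 cases and rose in 4 (12 adjusted over the list alone, median -0.28, adjusted p = 0.034). CA12 fell 13.9-fold and ANGPTL4 9.29-fold, while P4HA1 rose 4.24-fold and VEGFA 3.78-fold. That call was lost with an estimated correlation (adjusted p = 0.082).

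Among the largest rises, LOXL4 (at least 5137-fold, to 167 ± 7.46 CPM), PPP1R1B (at least 3321-fold), the gap junction gene GJA1 (at least 634-fold), EPDR1 (at least 544-fold), ATG9B (at least 522-fold) and RNF212 (at least 505-fold) were at 0 in A10. CDH19 had a ratio of 2723 (95% counting interval 488 to 107610). Among the largest falls, the lipoxygenase gene ALOX15B (at least 2612-fold), MYADM (at least 2204-fold), FGFR3 (at least 1855-fold) and VSTM2L (at least 1603-fold) were at 0 in CA1. S100A8 had a ratio of 23747 (4262 to 937987), and MT1E, a metallothionein with close paralogs, of 13039 (4461 to 63227). Of 29 lists, 16 passed with the preset correlation and 11 of them with an estimated one.

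T1 against NeoT compares consecutive lines of the series. All 22 epithelial junction genes were higher in T1 than in NeoT, and 16 of 22 mesenchymal markers were lower. KRT15 rose 4674-fold, from 1.08 ± 0.124 to 5110 ± 206 CPM, and COL17A1, a hemidesmosome collagen, 986-fold to 895 ± 17.9 CPM. The kallikrein genes KLK5 (at least 15793-fold higher, at 747 ± 17.9 CPM) and KLK7 (at least 15018-fold, 711 ± 18.8) had 0 counts in NeoT. FN1 fell 246-fold from 15980 ± 1763 to 65.1 ± 3.47 CPM and VIM 23.6-fold from 2235 ± 23.3 CPM. In all, 9718 genes changed, 5048 up and 4670 down, and 4399 of them by at least 2-fold (2470 up, 1929 down).

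All 22 epithelial junction genes rose (22 adjusted over the list alone, median 7.39, adjusted p = 7.4e-65), with ESRP1 up 1104-fold, CLDN1 741-fold, MAL2 61.7-fold and EPCAM 33.2-fold. Basal markers rose in 18 of 20 cases and fell in 2 (20 adjusted over the list alone, median 4.41, adjusted p = 9.6e-47), with KRT5 up 48.8-fold and LAMA3, a laminin chain, 27.5-fold. With an estimated correlation the camera adjusted p was 3.3e-04 for the junction genes and 5.2e-04 for the basal markers. Luminal markers rose in 14 of 16 cases and fell in 2 (16 adjusted over the list alone, median 4.28, or 4.19 with bounds, adjusted p = 3.8e-15), with CD24 up 187-fold, ELF3 136-fold and FOXA1 21.1-fold. Squamous genes rose in 14 of 19 cases and fell in 2 (16 adjusted over the list alone, median 7.06, or 5.62 with bounds, adjusted p = 1.4e-12), among them IVL (involucrin, 471-fold). Mesenchymal markers fell in 16 of 22 cases and rose in 3 (19 adjusted over the list alone, median -2.75, adjusted p = 1.1e-14), with DCN down 1386-fold, against a 39.1-fold rise of SPARC. Stromal fibroblast markers fell in 5 of 9 cases and rose in 1 (6 adjusted over the list alone, median -2.99, adjusted p = 3.5e-04), with C1R down 19.9-fold, while FAP rose 3.63-fold.

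Interferon-stimulated genes rose in 24 of 28 cases and fell in 1 (25 adjusted over the list alone, median 3.00, adjusted p = 2.9e-12), with IFIT2 up 49.2-fold, SAMD9 37.4-fold and IFI6 15.9-fold. S phase and mitosis genes rose in 28 of 30 cases and fell in 0 (28 adjusted over the list alone, median 0.98, adjusted p = 4.2e-06), with CDC6 up 4.003-fold, UHRF1 3.71-fold, PCNA 3.44-fold and PLK1 3.38-fold. NRF2 targets fell in 16 of 21 cases and rose in 2 (18 adjusted over the list alone, median -1.05, adjusted p = 1.5e-07), with AKR1C1 down 15.98-fold and NQO1 4.68-fold. MAPK feedback genes went both ways, 6 of 16 up and 7 down (13 adjusted over the list alone, median -0.15, adjusted p = 0.38). SPRY4 fell 4.51-fold and DUSP4 2.42-fold, while CCND1 rose 2.84-fold.

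EGFR ligands rose in 5 of 7 cases and fell in 2 (7 adjusted over the list alone, median 1.86, adjusted p = 0.0091), with HBEGF up 60.4-fold and EPGN 5.20-fold, while EREG fell 3.34-fold. With an estimated correlation the adjusted p was 0.0499959, and the call was lost without A10 replicate 1, 2 or 3 (adjusted p 0.11 to 0.14), libraries of a line outside this comparison. Serine synthesis and ATF4 targets rose in 15 of 22 cases and fell in 5 (20 adjusted over the list alone, median 0.79, adjusted p = 3.2e-04), with the amino acid transporter gene SLC7A5 up 19.0-fold from 90.1 ± 3.61 to 1714 ± 28.02 CPM and SLC7A11 4.79-fold. TGF-beta targets fell in 12 of 21 cases and rose in 5 (17 adjusted over the list alone, median -0.17, adjusted p = 0.021), with TGFBI down 8.06-fold, ID3 7.71-fold and ID1 5.16-fold and PMEPA1 up 5.37-fold. The serine and TGF-beta lists also had an adjusted p of 0.0499959 with an estimated correlation. Basement membrane and integrin genes fell in 14 of 24 cases and rose in 7 (21 adjusted over the list alone, median -0.62, adjusted p = 0.022), with ITGA5 down 12.3-fold and LAMB1 4.998-fold, while ITGB6 rose 1009-fold to 404 ± 13.9 CPM. The basement membrane call was lost with an estimated correlation (adjusted p = 0.28).

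Further large rises were KLK10 (at least 5871-fold), the mucin gene MUC16 (at least 3673-fold, to 174 ± 3.29 CPM), AP1M2 (at least 3070-fold), RAB25 (at least 2006-fold), SCEL (at least 1833-fold) and MPZL2 (at least 1503-fold). Large falls were SRGN (serglycin), with a ratio of 23295 (95% counting interval 4180 to 920147), the alcohol dehydrogenase gene ADH1B (at least 1931-fold), RTN1 (at least 466-fold), SFTPB (at least 351-fold), GPR173 (at least 316-fold), TNFAIP6 with a ratio of 2411 (667 to 19915) and GGT5 (1624-fold). Of the genes called in NeoT against A10, 7380 were called in the opposite direction in T1 against NeoT and 594 in the same, against 3424.6 and 3413.1 for independent lists. Both comparisons use the NeoT libraries, so part of the first excess may come from that. Of 29 lists, 13 passed with the preset correlation and 12 of them with an estimated one.

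CA1 against T1 compares the invasive line with the atypical hyperplasia line. Cholesterol synthesis was the gene group with the smallest camera p: 21 of 22 genes rose and 0 fell (21 adjusted over the list alone, median 1.69, adjusted p = 2.7e-37). HMGCS1 rose 13.8-fold, from 84.7 ± 3.91 to 1167 ± 18.7 CPM, INSIG1 9.01-fold, SQLE 5.76-fold and FDFT1 5.03-fold. LOXL4 stood at 167 ± 7.46 CPM in CA1 with 0 counts in T1 (at least 4703-fold higher), and PLAT (tissue plasminogen activator) rose 22.8-fold to 807 ± 30.9 CPM. MUC1 fell 413-fold from 213 ± 13.8 CPM, and CCND1 4.52-fold from 1174 ± 3.40 to 259 ± 9.66 CPM. In all, 8973 genes changed, 4379 up and 4594 down, and 3304 of them by at least 2-fold (1488 up, 1816 down).

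Fatty acid synthesis genes rose in 12 of 16 cases and fell in 1 (13 adjusted over the list alone, median 0.68, or 0.57 with bounds, adjusted p = 5.7e-05), with SCD up 5.43-fold, ACSS2 5.36-fold and FASN 2.21-fold. That call was lost with an estimated correlation (adjusted p = 0.051). NRF2 targets rose in 15 of 21 cases and fell in 5 (20 adjusted over the list alone, median 0.46, adjusted p = 0.012), with PIR up 4.22-fold and NQO1 2.96-fold; that call too was lost with an estimated correlation (adjusted p = 0.051). MAPK feedback genes rose in 12 of 16 cases and fell in 3 (15 adjusted over the list alone, median 1.29, adjusted p = 3.1e-05), with EPHA2 up 3.16-fold, PHLDA1 2.78-fold and DUSP4 2.70-fold. Antigen presentation genes rose in 10 of 18 cases and fell in 4 (14 adjusted over the list alone, median 0.57, or 0.51 with bounds, adjusted p = 0.0054), with HLA-B up 4.91-fold and B2M 1.94-fold. The antigen presentation call was lost with an estimated correlation (adjusted p = 0.29).

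Interferon-stimulated genes fell in 23 of 28 cases and rose in 2 (25 adjusted over the list alone, median -1.68, adjusted p = 1.4e-10), with IFI27 down 73.2-fold, IFIT2 28.9-fold and IFI6 14.04-fold. Squamous genes fell in 11 of 19 cases and rose in 3 (15 called when adjusted over the list alone, median -1.60, adjusted p = 6.8e-05). KLK7 fell 4070-fold and TGM1 42.9-fold, while SERPINB3 rose 30.8-fold. S phase and mitosis genes fell in 15 of 30 cases and rose in 6 (22 adjusted over the list alone, median -0.25, adjusted p = 1.4e-04), with UHRF1 down 5.13-fold, MCM4 4.28-fold and MCM3 3.94-fold. Luminal markers fell in 8 of 16 cases and rose in 4 (12 adjusted over the list alone, median -0.37, adjusted p = 0.021), with CD24 down 12.4-fold and KRT23 14.7-fold, while KRT18 rose 3.25-fold. The luminal call was lost with an estimated correlation (adjusted p = 0.070) and without A10 replicate 1, 2 or 3 (adjusted p 0.32 to 0.36). Inflammatory genes rose in 7 of 22 cases and fell in 10 (17 adjusted over the list alone, adjusted p = 0.54), with ICAM1 up 99.1-fold and IL1B 23-fold and SAA1 down 99.7-fold. Mesenchymal markers rose in 7 of 22 cases and fell in 12 (19 adjusted over the list alone, adjusted p = 0.54), among them VIM (up 3.86-fold) and SPARC (up 4.89-fold).

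Other genes at 0 in T1 were PRSS21 (at least 643-fold higher in CA1), the growth factor gene BMP7 (at least 352-fold), MYEF2 (at least 296-fold), LZTS1 (at least 296-fold) and APOBEC3F (at least 758-fold). APOBEC3G rose 1213-fold, and as APOBEC3F and APOBEC3G are close paralogs their reads may be shared. PLA2G4B was at least 273-fold higher at 10.1 ± 3.71 CPM and overlaps a readthrough gene. VSTM2L (at least 5805-fold, from 268 ± 19.3 CPM), MYADM (at least 1180-fold), ATP10A (at least 917-fold), ALOX15B (at least 815-fold), LPL (at least 527-fold) and the inflammasome adaptor gene PYCARD (at least 299-fold) were at 0 in CA1. The sodium channel gene SCNN1B had a ratio of 3840 (95% counting interval 1063 to 31714). Of 29 lists, 9 passed with the preset correlation and 5 of them with an estimated one.

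Some genes moved the same way in every derived line. Of those called in all 3 comparisons with A10, 1517 were higher and 1880 lower in NeoT, T1 and CA1 alike, 3397 in all, against 434.9 and 498.9 for independent lists. Among the shared rises whose smallest of 3 fitted changes was largest, EPDR1, GSPT2 and GJA1 had 0 counts in A10. For GJA1 the bounds were only at least 26-fold in NeoT and 10-fold in T1, so its place rests on fitted folds against 0 counts. EPDR1 stood at 33.8 ± 1.23, 40.6 ± 1.69 and 17.6 ± 3.11 CPM in NeoT, T1 and CA1. GSPT2 stood at 3.66 ± 1.26, 11.7 ± 1.37 and 8.51 ± 0.635, and GJA1 at 0.841 ± 0.353, 0.345 ± 0.204 and 20.7 ± 1.25. LY75, an endocytic receptor gene, stood at 59.5 ± 8.55, 109.8 ± 5.57 and 65.5 ± 3.59 CPM, and LAMA4 at 152 ± 22.4, 25.9 ± 1.57 and 351 ± 4.19, against 0.202 ± 0.217 in A10. PDPN (podoplanin, 46.2 ± 1.41 CPM in A10), FLI1 (12.8 ± 0.125), LARGE (12.7 ± 1.17) and EEF1A2 (12.2 ± 2.19) had 0 counts in every derived line, and PCSK1N (27.2 ± 2.54) had 0 counts in NeoT and T1 and a ratio of 1754 (95% counting interval 315 to 69309) in CA1. The 3 comparisons share the A10 libraries, so part of the excess over independent lists may come from them. Simulations of unchanged groups against the same A10 libraries gave 0 shared genes in each of 20 runs, which is chance with no effect and does not measure that part.

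By pairs, T1 and CA1 shared 5286 changes from A10 in the same direction and had 837 in opposite directions, NeoT and CA1 5918 and 1916, and NeoT and T1 4280 and 1638. Independent lists would give 2651.4 and 2651.9, 3601 and 3592, and 2630.8 and 2631.6 in that order. Each pair shares the A10 libraries, so part of the excess in the same direction may come with the shared reference. At all 3 consecutive steps, 129 genes rose and 77 fell, 206 in all, below the 516.2 and 546 of independent lists. Among the stepwise rises were WNK2 (582-fold higher in CA1 than in A10, at 47.0 ± 1.75 CPM), FIBCD1 (431-fold, 204 ± 15.3 CPM), ITGBL1 (212-fold), the retinol dehydrogenase gene DHRS9 (202-fold) and the chromatin remodeller CHD5 (ratio 1054, 95% counting interval 291 to 8708). Among the stepwise falls were S100A8 (362 ± 47.7 CPM in A10), SCARA3 (at least 784-fold), ABCA6 (at least 376-fold), the steroid dehydrogenase gene HSD17B2 (ratio 1989, 357 to 78578) and DOCK10 (ratio 354, 98 to 2928). Consecutive steps share a line, so a deviation of that line, by chance or real, pushes its 2 steps in opposite directions. The 2 steps that share NeoT had 7380 genes called in opposite directions and 594 in the same.

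**Figure D4:**
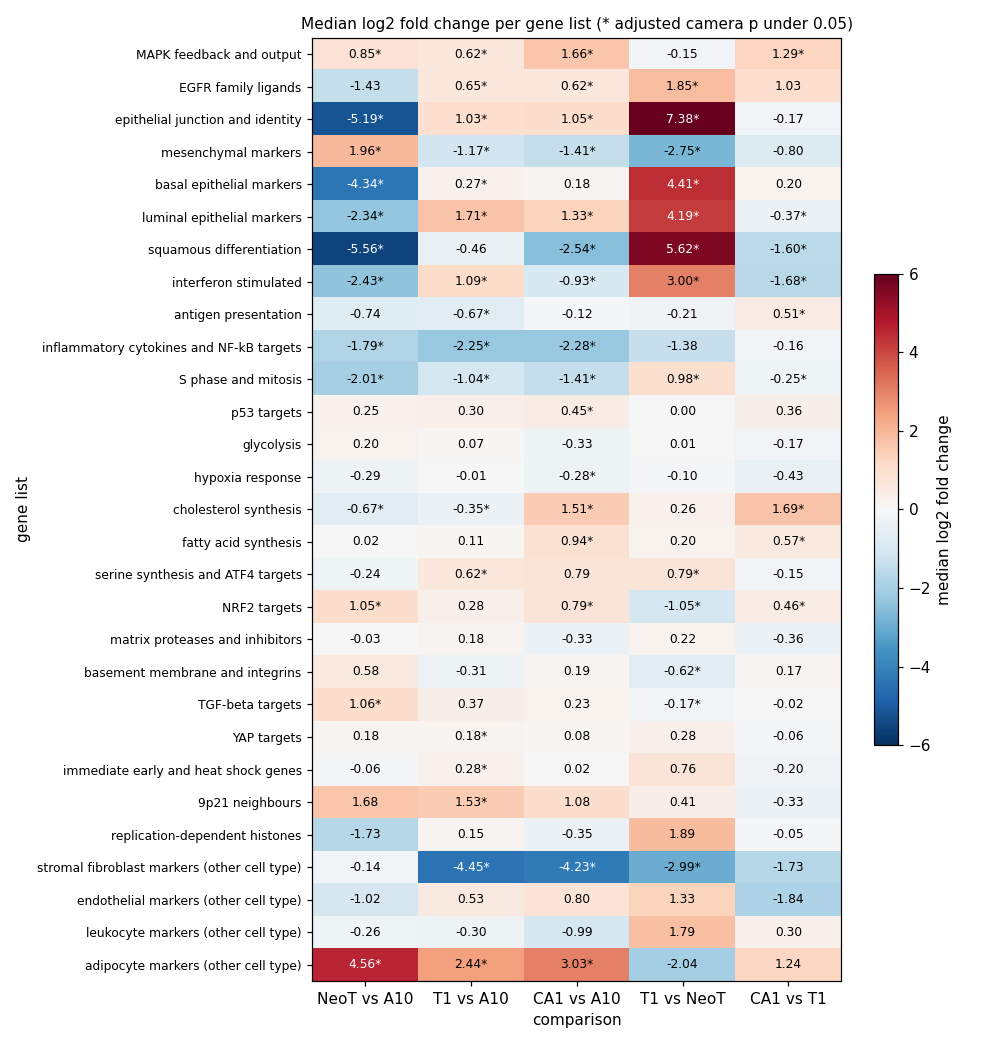
Median log2 fold change of each tested gene list (rows) in 5 comparisons (columns), with genes at 0 in a line placed at their bound; colours end at 6 in size, and a star marks an adjusted camera p under 0.05 with the preset correlation. Epithelial junction genes fall in NeoT (-5.19) and rise from NeoT to T1 (7.39), and cholesterol synthesis genes rise from T1 to CA1 (1.69).

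The lists that did not pass in any comparison were glycolysis, matrix proteases and inhibitors, replication-dependent histones, and the endothelial and leukocyte markers. Glycolysis genes had adjusted p of 0.94, 0.34, 0.97, 0.72 and 0.45 in NeoT, T1 and CA1 against A10, T1 against NeoT and CA1 against T1, although single members moved: SLC2A1, a glucose transporter gene, fell 5.10-fold in NeoT and HK2 rose 6.70-fold in CA1. Matrix proteases and inhibitors had adjusted p of 0.996, 0.30, 0.63, 0.48 and 0.89 in the same order, with SERPINE2 up 41.7-fold and TIMP1 6.16-fold in NeoT and PLAU down 20.4-fold. Histone genes had adjusted p of 0.42, 0.65, 0.97, 0.28 and 0.89. In NeoT against A10, 6 lists differed in sign between median, mean and test, in T1 against A10 2, in CA1 against A10 6, in T1 against NeoT 2 and in CA1 against T1 6. Of these, 0 had passed.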

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

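All tests of the NeoT epithelial genes and of the S phase genes below were chosen after the result was seen. The GRHL2 tests were set before their own outcome was seen, but for a pattern already found in these data. Several gene lists changed in opposite directions in different lines under the same comparison with A10, and the direct contrast between those lines gives the size of the difference. Lists are given here only where that contrast had passed too, so its p is not a separate test. Epithelial junction genes fell in NeoT and rose in T1 and CA1, with a median difference of 7.39 on the log2 scale for T1 against NeoT and 7.11 for CA1 against NeoT (adjusted p = 7.4e-65 and 3.05e-55, all 22 genes higher in both). With an estimated correlation these camera adjusted p were 3.3e-04 and 3.9e-04. Mesenchymal markers did the reverse, at -2.75 for T1 (adjusted p = 1.1e-14, 16 of 22 lower) and -3.79 for CA1 (adjusted p = 4.91e-14, 19 of 22 lower). Luminal markers differed by 4.28 (adjusted p = 3.8e-15, 14 of 16 higher) and 3.20 (adjusted p = 2.97e-08, 13 of 16 higher). Interferon-stimulated genes fell in NeoT and rose in T1, a difference of 3.00 (adjusted p = 2.9e-12, 24 of 28 higher). Cholesterol synthesis genes fell in NeoT and T1 and rose in CA1, a difference of 2.09 from NeoT (adjusted p = 2.14e-20, 21 of 22 higher) and 1.69 from T1 (adjusted p = 2.7e-37, 21 of 22 higher). In T1 replicate 1, cytoplasmic rRNA, a class that the gene comparisons do not describe, took 7.76% of the counts (95% Wilson interval 7.754% to 7.773%), against 2.18% in the next highest library, NeoT replicate 1 (2.174% to 2.185%). Leaving the rRNA rows out, or this library, is covered by the alternatives below.

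In the NeoT libraries most epithelial and basal genes were far lower than in A10. Fibroblasts in place of nearly all cells would bring their abundant transcripts, with at least 100 CPM set as the bound, and the highest value among COL1A1, COL1A2 and SPARC in a NeoT library was 8.5 CPM, which argues against them. Mesenchymal cells of another kind could not be excluded. DCN (632 ± 34.0 CPM), LOX and FN1 were higher in NeoT than in A10, as were 6 adipocyte markers. The adipocyte call was lost with an estimated correlation (adjusted p = 0.072), and 4 of 6 were also higher in T1 and 5 of 6 in CA1, so a rise as such is not particular to NeoT. Set directly against NeoT, 4 of 6 were lower and 2 higher in T1 (median -2.04). The same numbers held in CA1 (median -2.06). The list was called in neither contrast (camera adjusted p = 0.46 and 0.68). A swap of single NeoT libraries with libraries of another line would give a correlation like that between replicates, at least 0.9776, and the highest was 0.8443. An exchange of all 3 NeoT libraries with all 3 of another line would leave these correlations as they are. HRAS was higher in every library of 3 lines, NeoT, T1 and CA1, than in A10, so an exchange with T1 or CA1 cannot be told apart from correct labels by it. An error of scaling between libraries would move all genes alike, and the epithelial median lay -5.467 from the median of all tested genes, which argues against it. That the libraries come from a line of other origin could not be excluded. CDKN2A, CDKN2B and CDKN2B-AS1, a locus that MCF10A cells lack, had 0 counts in NeoT, which is what a descendant of MCF10A and another line without the locus would both show. The neighbouring MTAP stood at 1.75 CPM in NeoT and 0.0953 in A10 (17.1-fold), and at 0.574 in T1 and 3.35 in CA1, so it does not set NeoT apart from the other derived lines. The difference between the lines that the design names, with the mutant HRAS, stays open and untested, and T1 and CA1, which descend from the same cells, did not share the pattern.

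The S phase and mitosis genes were lower in NeoT, T1 and CA1 than in A10. An error of scaling between libraries would move all genes alike, and is argued against by the differences between the list median and the median of all tested genes, the highest of which was -1.038. A high level in the A10 libraries could not be excluded for the fall common to the 3 lines. The 3 medians, the highest at -1.05, all rest on the same A10 libraries. As the whole account it is argued against, since A10 would not make the derived lines differ from each other. In T1 against NeoT 28 of 30 genes rose and 0 fell (median 0.98, camera adjusted p = 4.2e-06). In CA1 against T1 15 fell and 6 rose (median -0.25, camera adjusted p = 1.4e-04). The growth state of the cultures at harvest may explain the pattern and cannot be told apart from the lines, because 0 labels give density or time at harvest. A difference in growth between the lines themselves stays open and untested.

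GRHL2 had 0 counts in every A10 and NeoT library and 59.0 ± 2.59 CPM in T1. Loss of the surrounding region of 8q22 in A10 would lower its neighbours, but 6 genes within 1 Mb with at least 10 CPM in T1 had a median of -0.14 for T1 against A10, so they were not lower in A10. Reads shared with GRHL1 or GRHL3 could move counts between the genes, but these stood only 17.8 CPM higher in A10 than in T1, less than the GRHL2 level in T1. With both argued against, a candidate explanation is that the gene is silent in A10 and NeoT and active in T1 and CA1. This is a hypothesis found and tested on the same data, and a loss of GRHL2 alone was not tested.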

How the results depend on the processing

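The fits without rRNA rows and without both T1 replicate 1 and NeoT replicate 3 were chosen after seeing the data. No named gene or list called in the main fit reversed its direction under any alternative run. Lists not called there could change direction. With fry, YAP targets in NeoT against A10 and TGF-beta targets in CA1 against T1 went down, where camera had them up. The counts of called genes stayed within 1.5 times their value in every alternative except glmTreat in 2 comparisons, which tests against a 2-fold change and so asks for more than a fitted 2-fold difference. It gave 1699 genes for T1 against A10 in place of 2716 and 2014 for CA1 against T1 in place of 3304.

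Leaving out a library in turn gave 9573 to 10367 genes for NeoT against A10, 6689 to 8464 for T1 against A10, 9670 to 10856 for CA1 against A10, 9159 to 10019 for T1 against NeoT and 8185 to 9774 for CA1 against T1. The other alternatives gave 9434 to 10349, 7232 to 8163, 9779 to 10852, 8892 to 9859 and 8710 to 9668 in that order. The 8464 came without NeoT replicate 3. In the fits to only the 2 lines compared, the spread was not shared with the other lines. Comparisons with NeoT gave fewer genes there. NeoT against A10 had 9434 in place of 10144, and T1 against NeoT 8892 in place of 9718. The others gave more: 8163 in place of 7479 for T1 against A10 and 10623 in place of 10223 for CA1 against A10. CA1 against T1 had 9668 in place of 8973. T1 replicate 1 and NeoT replicate 3 were doubted because chi-square per degree of freedom with their replicates was 99.9 and 69.9, and 40.6 and 29.1, against 5.49 to 13.1 in the other pairs. The chi-square included the cytoplasmic rRNA rows and was not taken without them, so the values of T1 replicate 1 may reflect its 7.76% rRNA. Its Pearson's r with T1 replicates 2 and 3 was 0.9863 and 0.9831, against 0.9839 between T1 replicates 2 and 3. Without both doubted libraries, the counts were 10349, 7886, 10852, 9672 and 9259. Genes differing among the 4 lines numbered 12274 to 13529 over the alternatives other than glmTreat and the fit to only the 2 lines compared, which give no value here, those shared by the 3 comparisons with A10 3007 to 3806, and those changed at all 3 steps 172 to 239. Which direction held more genes depends on the setting in 2 comparisons. T1 against NeoT had 4745 genes up and 5049 down with upper-quartile factors. T1 against A10, with 50.18% of its called genes up, had 47.89% with upper-quartile factors, 48.96% with no filter, 49.36% with limma-voom, 48.76% with only the 2 lines compared, and 49.1% without both doubted libraries. Its share was 49.65% to 49.96% up without NeoT replicate 1, 2 or 3, T1 replicate 1 or CA1 replicate 1, 2 or 3. Its genes of at least 2-fold, 1362 up and 1354 down, were as close to even.

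For replicate agreement, Spearman's rho had a median of 0.9954 and Pearson's r over genes of at least 10 CPM 0.992, against 0.9864. Both moved by more than 1 SD of the 12 pairs. Spearman works on ranks and the other leaves out weakly expressed genes. The permutation p of the mitochondrial rRNA share ran from 6.494e-05 to 2.6e-04.

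The rules for naming genes picked 308, as 675 pairs of a gene and a comparison, of which 667 were called. Over their alternatives, 14786 of 14828 values stayed on their side of the threshold, 30 lost the call and 12 gained it. For the lists, apart from fry, 2258 of 2320 stayed, 43 lost it and 19 gained it. Over the 145 pairs of a list and a comparison, an estimated correlation in camera ended 15 calls, and fry, which does not compare a list with other genes, added 64. The replicate numbers did not pair the libraries: residual correlations between libraries of the same number had a median of -0.025, and 4 of 12 libraries correlated best with their own number. With the number as a block, 2 of 675 gene calls were lost, and of the 145 list results 11 lost the call and 3 gained it. The calls lost were luminal markers in NeoT against A10, basal markers and YAP targets in T1 against A10, EGFR ligands, squamous and hypoxia genes in CA1 against A10, EGFR ligands, TGF-beta targets and stromal markers in T1 against NeoT, and luminal and squamous genes in CA1 against T1 (adjusted p 0.058 to 0.66). Those gained were antigen presentation in NeoT against A10 and serine synthesis and 9p21 neighbours in CA1 against A10 (adjusted p 0.013 to 0.018).

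Depth limits the genes at 0 in a line, whose folds are bounds against 3 counts over the line. DESeq2 gave no adjusted p for 5 genes in each comparison.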

Other observations

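The test of neighbouring genes and the splits of the libraries were set before their results were seen. Only protein-coding genes were counted here, so unmatched rows were left out. Those with 0 counts in a line and at least 10 CPM in another were most frequent for NeoT: 33 of them were on in A10, 41 in T1 and 46 in CA1. For A10 the numbers were 2 in NeoT, 7 in T1 and 8 in CA1, for T1 12 in A10, 4 in NeoT and 7 in CA1, and for CA1 25 in A10, 28 in NeoT and 9 in T1. With 0 counts in NeoT and at least 10 CPM in each of the other lines there were 10 genes (AP1M2, DAPP1, EPHA1, KLK5, MACC1, MPZL2, MUC16, RNF43, SCEL and TP63). For CA1 there were 4 (ALOX15B, MYADM, SULT1E1 and VSTM2L), for A10 1 (EPDR1) and for T1 0. These lists were drawn up by this criterion after values had been seen. The level of 3 counts over a line was higher in NeoT (0.0474 CPM) and CA1 (0.0463) than in A10 (0.0326) and T1 (0.0356). Depth may therefore add to the zeros of NeoT and CA1.

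Neighbouring genes changed together more than their order by chance would give. In CA1 against A10, 47 of 225 windows of 10 Mb had a median log2 fold change over 0.3 in size, against a mean of 20.21 and a maximum of 35 in 1000 shufflings of gene order (p = 0.001, permutation test, the smallest that these can give). In the other comparisons 53 windows passed for NeoT against A10, 21 for T1 against A10, 31 for T1 against NeoT and 26 for CA1 against T1, each with the same p. On chromosome 1, the window from 240000001 to 250000000 (32 genes) had medians of -0.98, -1.05 and -1.11 in NeoT, T1 and CA1 against A10, and that from 220000001 to 230000000 (61 genes) -1.05, -0.96 and -0.96. All windows of that chromosome from 140000001 to 190000000 and from 200000001 to 250000000 had negative medians in every derived line. Those medians ran from -0.158 to -1.248 in NeoT, -0.515 to -1.05 in T1 and -0.314 to -1.11 in CA1. How many of the genes lower in every derived line lie in these windows was not counted. On chromosome 9, the window from 1 to 10000000 (27 genes) had medians of 0.36, 1.09 and 1.199 in NeoT, T1 and CA1. The window from 30000001 to 40000000 (75 genes) had 0.642, 0.509 and 0.503. On chromosome 19, windows from 30000001 to 60000000 had 0.507 to 0.73 in NeoT, 0.502 to 0.575 in T1 and 0.004 to 0.014 in CA1. On chromosome 3, windows from 100000001 to 160000000 and from 170000001 to 200000000 had 0.361 to 0.761 in CA1. The same windows had -0.233 to 0.292 in NeoT and -0.054 to 0.087 in T1. These stretches were picked after the values were seen. Chance order is argued against. A difference in DNA copy number between the lines may explain such windows, as may shared regulation of neighbours, and the series holds no DNA data to tell these apart.

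Each comparison of a pair of lines has only 10 splits of its 6 libraries, too few for a share under 0.05. The real split was the 1 with the highest count in each. It gave 10144 genes (4942 of at least 2-fold) for NeoT against A10, 7479 (2716) for T1 against A10, 10223 (4908) for CA1 against A10, 9718 (4399) for T1 against NeoT and 8973 (3304) for CA1 against T1, and the highest other split gave 0 in each. For the 12 libraries, 1 of 100 splits, the real one, gave as many genes differing among the lines (12953, highest other 3598) and as many shared by the 3 comparisons with A10 (3397, highest other 2758), so chance can be excluded for these only in the sense that the lines differ. The splits do not show that the sharing exceeds what the A10 libraries give to all 3 comparisons. For genes changed at all 3 steps the real split gave 206 and the highest other 0. Splits that mix lines widen the spread within groups, which lowers the other counts here and above, so this does not show that 206 exceeds chance, and the number lies below that for independent lists.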
